A study of Mus musculus with 48 samples.

How the data were processed

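The series holds bulk 3′ sequencing of poly(A) RNA from immune cells sorted out of mouse colon tumours, with a sample barcode per library, after a modified published protocol, per the labels' protocols. The deposited table holds 1 whole-number count per gene symbol and library, with no normalization recorded by the authors. The genome build was GRCm38, and R 3.4.4 and DESeq2 1.18.1 were used, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the barcode handling are not given in the sources used here. It is not stated whether the counts are of molecular identifiers or of reads, so every floor given here covers counting error only.

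The table has 24538 gene rows, of which 15856 (64.6%) carry a symbol of GENCODE release M21 (GRCm38), the source of all coordinates. Rows without such a symbol hold 1227913 counts (9.35%) and were kept under the name the table gives. One row named z, with 127 counts (0.000967%), names no gene and was not removed. All 48 columns matched the labels. The highest row holds 412899 of 13126899 counts (3.15%). Some genes of the lists are not analysed here, and mitochondrially encoded genes and those for most MHC class II chains are among them.

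Groups were taken from the labelled population and genotype. In Ly6Clo MHCIIhi, 4 replicates per genotype had a second library under the same replicate number, and the counts of both libraries were added. Libraries under 0.1 of the median total, that is under 28006.25 counts, were left out, which removed 1. Nothing in the labels says that replicates are separate animals, so p-values measure the spread between these samples. Housing is not labelled per sample and was not modelled.

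Levels are CPM, counts as a rate over library sizes scaled by TMM (edgeR 4.0.16 in R 4.3.3), with SD over replicates. Genes were kept for a comparison by filterByExpr with a minimum count of 10 and a minimum total of 15. Differences were tested with the quasi-likelihood F test of edgeR and Benjamini-Hochberg adjustment over all genes of a comparison, and an adjusted p under 0.05 counts as past the threshold. Every adjusted p of a single gene in the text comes from this test unless another is named, and folds are log2 with their standard errors (SE). Labelled ko was compared with labelled ctrl in each population. Pairs of populations that share a level of Ly6C or MHC class II were compared with genotype in the model. The interaction of population and genotype was tested with 3 coefficients at the same time. Ccl17 was under the count filter in the genotype comparisons, so it was tested by a two-sided exact permutation test of mean log2(CPM + 1), with a floor of 3 counts for values of 0.

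In all, 32 gene lists with 580 genes were fixed with the tests, the filters and the naming rule before the data were examined, and 28 lists had at least 3 tested members in some comparison. Lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. A count given as adjusted over the list alone uses only the members' own p-values. Summed marker levels of 9 other cell types were compared by exact permutation tests, adjusted over lists and populations.

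Genes are named by rule. The rule takes up to 10 per direction with the largest fold among those past the threshold that reach 20 CPM in the higher group and differ the same way in every replicate, or in at least 0.75 of them where a group has more than 4. It adds the sort markers, and up to 4 members past the threshold with the smallest p of each list that passed camera. Where fewer than 5 passed in a direction, the 5 with the smallest p are named as not passing. Predicted genes and antigen receptor segments are not named, except where 5 or fewer genes passed. Some genes that meet the rule are not reported here. The members named for lists in the genotype comparisons were chosen after their values were seen.

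Whether equal replicate numbers pair the samples was checked by the correlation of their deviations from the group means. Only in Ly6Chi MHCIIhi against MHCIIlo did every pair exceed 0.1 (7 of 7 pairs, 0.101 to 0.448), so a fit with the number as a block is given there where it changes a call.

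Alternatives were DESeq2 size factors, the DESeq2 1.42.0 test, no count filter, all libraries kept, library 1 only, each library as its own sample, the number set (1 to 4 against 5 to 8) as a covariate with library 1 only in Ly6Clo MHCIIhi ko against ctrl (there the same model as barcode class), a block for the replicate number, all 8 groups in 1 fit, samples labelled ctrl only, pseudocounts of 0.5 and 5 in place of 1, and leaving out each replicate. Added after seeing the data were the pooled fit (all 8 groups in 1 fit with each library as its own sample), the same fit with barcode class, a fit without libraries under 100000 counts and the block for the interaction. In the pooled fits the libraries of one replicate count as separate samples, and barcode class is told apart from genotype only by Ly6Clo MHCIIhi. A barcode was called G/C-rich with 3 or more G or C of 6 bases.

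Only the single-gene test was run on simulated counts, filtered genes counting as not recovered. There 100 genes were changed 2-fold and 100 4-fold. For labelled ko against ctrl, 7% and 68% of these were recovered in Ly6Chi MHCIIhi (3553 genes), 36% and 87% in Ly6Chi MHCIIlo (3966), 79% and 76% in Ly6Clo MHCIIhi (5660) and 43% and 87% in Ly6Clo MHCIIlo (3182). For populations, 49% and 94% were recovered in Ly6Chi MHCIIhi against MHCIIlo (4756), 79% and 88% in Ly6Clo MHCIIhi against MHCIIlo (4817), 76% and 82% in Ly6Clo against Ly6Chi MHCIIhi (5541) and 69% and 85% in Ly6Clo against Ly6Chi MHCIIlo (4336). The interaction gave 32% and 90% (6022), rates that an effect in Ly6Chi MHCIIhi alone need not reach. Wrong calls made up 1.76% to 7.41% of all calls.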

Results

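Poly(A) transcripts were counted in immune cells sorted from colon tumours of mice. The tumours were induced with azoxymethane, a carcinogen, together with dextran sulfate sodium, which injures the colon lining and causes colitis, and the samples are labelled day 85. The design compares mice labelled ctrl with mice labelled ko for Ccl17, which encodes a chemokine that dendritic cells release and that attracts cells bearing the receptor CCR4. Cells were sorted into 4 populations by Ly6C, a surface protein abundant on blood monocytes, and by MHC class II, which presents antigen to T cells. The 48 libraries fall into 8 groups of population and genotype. Ly6Chi MHCIIhi, Ly6Chi MHCIIlo and Ly6Clo MHCIIlo had 4 replicates per genotype, and Ly6Clo MHCIIhi had 8 per genotype, of which 4 had a second library, added to the first. The series names ko mice cohoused with controls and ko mice housed separately, and housing is not given per sample.

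Total counts per library ran from 8409 to 500687, with a median of 280062.5. Labelled ctrl and labelled ko libraries held 8409 to 243342 and 132803 to 290635 counts in Ly6Chi MHCIIhi, and 222561 to 314178 and 234306 to 388820 in Ly6Chi MHCIIlo. The ranges were 51630 to 468742 and 39872 to 500687 in Ly6Clo MHCIIhi, and 139098 to 248596 and 170909 to 234647 in Ly6Clo MHCIIlo. The library of 8409 counts, Ly6Chi MHCIIhi ctrl replicate 2, was left out of all comparisons, so that group had n = 3. The MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 are not analysed here, and Ly6c1 was under the count filter, so the gates were read from Ly6c2 and from Cd74, the chaperone of MHC class II.

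Ccl17 (chromosome 8, 94810453 to 94812036, plus strand, GRCm38) was counted first, because it checks the genotype labels. In Ly6Clo MHCIIhi it stood at 170 ± 269 CPM (SD, n = 8) in replicates labelled ctrl and at 3.22 ± 2.67 CPM (SD, n = 8) in those labelled ko. These levels rest on 510 of 3747690 counts and on 15 of 4094410 counts. Labelled ctrl replicates 1 to 8 held 6.56, 101, 0, 763, 362, 112, 1.45 and 9.66 CPM. Labelled ko replicates 1 to 8 held 4.04, 4.97, 0, 1.25, 7.47, 0, 2.92 and 5.09 CPM. Thus 5 of 8 replicates labelled ctrl lay above the highest labelled ko, replicate 8 of them only just, and replicates 1, 3 and 7 lay within the ko range, so groups are named by their labels throughout. The 0 in ctrl replicate 3 allows up to 19.6 CPM of the library total, and those in ko replicates 3 and 6 allow up to 9.39 and 75.2 CPM. The difference in mean log2(CPM + 1) was -3.18, with a two-sided exact permutation p of 0.0331 and an adjusted p of 0.132 over the 4 populations. The deleted part of Ccl17 is not given in the sources used here, and a 3′ tag outside it would check nothing.

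The exact p for Ccl17 in Ly6Clo MHCIIhi rose above 0.05 when ctrl replicate 2 (0.058), 4 (0.062), 5 (0.06) or 6 (0.0587), or ko replicate 3 or 6 (0.0549 each), was left out. The Ccl17 level difference ran from -2.51 without ctrl replicate 4 to -3.88 without ctrl replicate 3, and the ctrl mean was 84.7 CPM without ctrl replicate 4. In Ly6Chi MHCIIhi, Ccl17 stood at 10.3 ± 14.2 CPM (SD, n = 3) in labelled ctrl and 4.85 ± 5.91 CPM (SD, n = 4) in labelled ko (exact p = 0.657). The values were 12.2 ± 11.7 and 4.26 ± 4.10 CPM (SD, n = 4 each) in Ly6Chi MHCIIlo (exact p = 0.457). In Ly6Clo MHCIIlo they were 0.933 ± 1.87 and 5.88 ± 5.96 CPM (SD, n = 4 each; exact p = 0.143). These levels rest on 1 to 14 counts per group and move with single replicates. The means became 2.18 without Ly6Chi MHCIIhi ctrl replicate 1, 2.46 without ko replicate 4, 2.42 without Ly6Chi MHCIIlo ko replicate 1, 0 without Ly6Clo MHCIIlo ctrl replicate 3 and 3.13 without ko replicate 2. Hence a loss of Ccl17 was not detectable there at this depth.

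**Figure D1:**
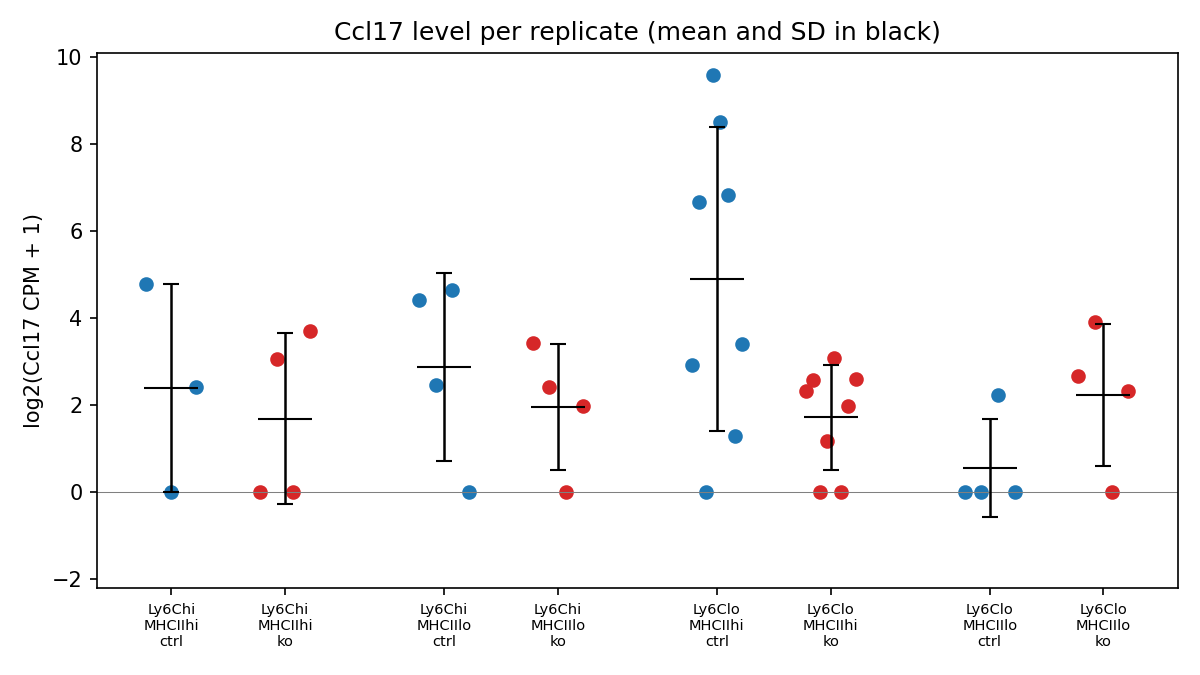
Ccl17 in log2(CPM + 1) for every replicate by population and genotype label, with group means and SD bars. In Ly6Clo MHCIIhi the 8 replicates labelled ctrl spread from 0 to 763 CPM and no replicate labelled ko is above 7.47 CPM.

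The comparison of labelled ko with labelled ctrl in Ly6Clo MHCIIhi asks how loss of Ccl17 alters the population in which its transcript was found. No single gene passed the threshold. As gene groups the immediate early, NF-kB target, haemoglobin and macrophage genes stood apart from other genes by camera, a test of a list against all other genes, but none did when the correlation between genes was estimated (smallest adjusted p = 0.148). Immediate early and heat shock genes, which cells switch on within minutes of stimulation or handling, had a median log2 fold change of -0.35 over 16 members. Adjusted over the list alone, 11 were lower and 0 higher in labelled ko. Egr1, a growth-factor-induced transcription factor, stood at 338 ± 38.1 CPM (SD, n = 8) in labelled ko and 560 ± 238 CPM (SD, n = 8) in labelled ctrl (log2 fold change -0.69, SE 0.18, adjusted p = 0.888). Jun, a subunit of the AP-1 factor, stood at 1496 against 2242 CPM (-0.57, SE 0.16). Inflammatory cytokines and NF-kB targets had a median of -0.42 over 17 members, among them Ptgs2, which makes prostaglandins (-1.12), Il6, a cytokine of acute inflammation (-0.96), Ccl3, a macrophage chemokine (-0.89), and Tnfaip3, a brake on NF-kB (-0.50).

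The 4 haemoglobin genes, transcripts of red cells, had a median log2 fold change of 2.17 in Ly6Clo MHCIIhi, and adjusted over the list alone all 4 were higher in labelled ko. Hbb-bs, a beta globin gene, stood at 1428 ± 1915 CPM in labelled ko and 241 ± 288 CPM in labelled ctrl (SD, n = 8 each). Without ko replicate 6, which held 39872 counts, the ko mean was 771.5 CPM and the log2 fold change 1.51 for 2.25. Haemoglobin also differed up to 39.7-fold between the libraries of a single replicate. Reads may be shared between the near-identical copies, so each haemoglobin gene alone is uncertain. Mature macrophage genes had a median of 0.17 over 16 members, among them Adgre1, which encodes F4/80 (0.48), Cd63, a lysosomal tetraspanin (0.46), and Fcgr1, a high-affinity IgG receptor (0.32). Tumour-associated macrophage genes had a median of 0.18 over 13 members, lysosome genes 0.15 over 21 and oxidative phosphorylation genes 0.12 over 32. B and plasma cell genes had a median of -1.91 over 3 members, the immunoglobulin genes Igkc (-2.29) and Igha (-1.70) and the joining chain gene Jchain (-1.90), each lower when adjusted over the list alone. These 8 of 27 lists passed camera. The adjusted p was 5.32e-14 for immediate early, 5.51e-06 for NF-kB, 2.05e-07 for haemoglobin, 5.7e-05 for macrophage, 0.00811 for tumour-associated macrophage, 4.22e-05 for lysosome, 2.82e-07 for oxidative phosphorylation and 0.0138 for B and plasma cell genes. With an estimated correlation it was 0.148 for the immediate early and haemoglobin lists and 0.375 for the others. The B and plasma cell call also ended without ctrl replicate 8 (0.0516) or ko replicate 5 (0.0907), 7 (0.0667) or 8 (0.0759). In the pooled fit, of all 8 groups with each library as its own sample, it had adjusted p = 0.00104, and 0.341 when barcode class was added.

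Of 5660 genes tested in Ly6Clo MHCIIhi, edgeR and DESeq2 called 0. An unadjusted p under 0.05, which chance gives in about 1 of 20, was held by 296. The smallest p belonged to Map3k14, the kinase that starts alternative NF-kB signalling, at 59.2 ± 11.7 CPM in labelled ko and 105 ± 22.0 CPM in labelled ctrl (SD, n = 8 each). Its log2 fold change was -0.73 (SE 0.15, lower than the ctrl mean in 8 of 8 ko replicates, adjusted p = 0.35). The other lower genes with small p were Phkg2, a phosphorylase kinase subunit (-0.75), Yy1, a zinc finger factor (-0.63), and Uvrag, which acts in autophagy (-0.60). The higher genes were Ms4a6d, a macrophage membrane protein (0.45), Fcer1g, the signalling chain of Fc receptors (0.25), Retnlg, a neutrophil gene (1.58), and Nr1h3, the oxysterol receptor LXR alpha (0.66). None of these passed (adjusted p = 0.888 each). With the replicates labelled ctrl that lay within the ko range of Ccl17 kept in, these folds compare labels, not measured Ccl17.

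In Ly6Chi MHCIIlo, the comparison of labelled ko with labelled ctrl asks about monocytes low in MHC class II. Here 3 of 3966 genes passed, all lower in labelled ko. Dpysl2, a regulator of microtubules, stood at 45.1 ± 18.4 CPM in labelled ko and 176 ± 62.9 CPM in labelled ctrl (SD, n = 4 each; log2 fold change -1.97, SE 0.34, adjusted p = 0.0416). Gas7, which shapes the actin network, stood at 62.0 ± 2.16 against 205 ± 62.6 CPM (-1.72, SE 0.26, adjusted p = 0.017). The unnamed locus RP24-159O13.1, given because the count is small, stood at 18.2 ± 7.71 against 109 ± 33.3 CPM (-2.54, SE 0.35, adjusted p = 0.0125). All 3 were lower in 4 of 4 replicates. Of genes that did not pass, Map3k1, a stress kinase (-2.36), Tmem88, a Wnt pathway protein (-1.94), Dusp3, a phosphatase (-1.17), Plxnb2, a semaphorin receptor (-1.0), and Plec, a cytoskeletal linker (-0.90), had adjusted p between 0.11 and 0.122. On the higher side were Tgm2, a protein cross-linking enzyme of alternatively activated macrophages (0.96, 4538 against 2335 CPM), Lypd8, a colon epithelial protein (1.90), Ednrb, an endothelin receptor (1.02), Bcl2a1b, a survival factor (0.85), and Sdc1, a proteoglycan (0.92), with adjusted p from 0.155 to 0.185. At an unadjusted p under 0.05 there were 444 genes, and DESeq2 called 14.

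In Ly6Chi MHCIIlo, immediate early genes had a median log2 fold change of -0.44 over 16 members, and 4 were lower when adjusted over the list alone. Klf2, a factor that keeps myeloid cells quiescent, stood at 877 against 2026 CPM (-1.20, SE 0.30, adjusted p = 0.185), and Jun had a log2 fold change of -0.81. Oxidative phosphorylation genes had a median of 0.27 over 31 members. The adjusted camera p was 2.48e-06 and 6.95e-08, and 0.649 for both with an estimated correlation. NF-kB targets (median -0.21, adjusted p = 0.0173), ribosomal proteins (0.13, 0.0153), epithelial (0.65, 0.0273), haemoglobin (2.03, 0.0397) and tumour-associated macrophage genes (0.46, 0.0495) passed as well. With an estimated correlation their adjusted p was 0.649 for NF-kB targets, 0.799 for ribosomal proteins and 0.697 for the others. In the pooled fit the epithelial (0.00193) and ribosomal lists (0.000607) passed and lost the call when barcode class was added (0.201 and 0.0754), whereas NF-kB targets (0.103), haemoglobin (0.141) and tumour-associated macrophage genes (0.0683) did not pass in either. The calls of these 5 lists ended in 2 to 6 of 8 leave-outs. The highest adjusted p was 0.127 without ctrl replicate 3 for NF-kB, 0.368 without ko replicate 4 for ribosomal, 0.153 without ctrl replicate 3 for haemoglobin, and 0.151 and 0.259 without ko replicate 2 for the epithelial and tumour-associated macrophage lists.

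In Ly6Clo MHCIIlo, the comparison of labelled ko with labelled ctrl asks about cells low in Ly6C and MHC class II, in which macrophage and neutrophil transcripts were abundant. Dpysl2 was again lower in labelled ko, at 82.0 ± 26.8 against 265 ± 38.2 CPM (SD, n = 4 each; log2 fold change -1.67, SE 0.25, lower in 4 of 4, adjusted p = 0.0149). It was the only one of 3182 genes that passed in edgeR, with 136 at an unadjusted p under 0.05 and 2 in DESeq2. The haemoglobin genes had a median of 2.62, and all 4 were higher when adjusted over the list alone. Hba-a2, an alpha globin gene, stood at 633 ± 484 against 81.2 ± 101 CPM (2.90, SE 0.58, adjusted p = 0.108), with means of 397.7 without ko replicate 2 and 31.38 without ctrl replicate 1. Hba-a1 (2.70), Hbb-bs (2.54) and Hbb-bt (2.45) followed, with Pfkfb4, a regulator of glycolysis (1.29). Lower without passing were Dhrs3, a retinaldehyde reductase (-1.45, 101 against 274 CPM, adjusted p = 0.108), Ptafr, the receptor for platelet-activating factor (-1.03), Kdelr2, a retrieval receptor of the endoplasmic reticulum (-0.99), Tram1, a translocation protein (-0.86), and Dusp3 (-0.82). Neutrophil genes had a median of 0.65 over 15 members, with an adjusted camera p of 2.76e-07, against 9.21e-11 for haemoglobin genes. With an estimated correlation these were 0.374 and 0.237. In the pooled fit they were 0.000473 and 0.00262, and 0.337 and 0.000588 when barcode class was added. Monocyte (median 0.23, adjusted p = 0.006), epithelial (0.20, 0.00887), bacterial sensing (0.23, 0.0339) and immediate early genes (-0.17, 0.000989) passed too, each with adjusted p = 0.502 with an estimated correlation. In the pooled fit the monocyte (0.0284) and immediate early lists (0.00938) passed and lost the call when barcode class was added (0.36 and 0.434), whereas the epithelial (0.203) and bacterial sensing lists (0.442) did not pass in either. The monocyte call ended without ctrl replicate 3 (0.113) and the immediate early call without ctrl replicate 2 (0.128). The epithelial call ended without ctrl replicate 1 (0.946) or ko replicate 3 (0.0871), and the bacterial sensing call without ctrl replicate 1 (0.0612), ctrl replicate 3 (0.358) or ko replicate 3 (0.428).

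Each library carried a 6-base barcode. In the populations with 4 replicates per genotype every labelled ctrl library had an A/T-rich and every labelled ko library a G/C-rich barcode, so barcode class and genotype cannot be told apart there. In Ly6Clo MHCIIhi 8 of 12 ctrl and 4 of 12 ko libraries were A/T-rich. There a fit of library 1 of 16 replicates found 80 of 4510 genes differing between barcode classes, 76 lower with G/C-rich barcodes. In that fit replicates 1 to 4 were A/T-rich and 5 to 8 G/C-rich, so these sets cannot be told apart from barcode class. By edgeR 0 differed between genotypes in the same fit (211 at an unadjusted p under 0.05), while the pooled fit with barcode class called 2 there. Within the 5 replicates that had a library of each class, where differences between replicates cancel but the G/C-rich library was library 1 in 4 of 5, 89 of 4945 genes differed, 82 of them lower in the G/C-rich library, with Dpysl2 (log2 difference -2.38, SE 0.15) and Gas7 (-1.30, SE 0.17) among these. Of the genes listed without passing, Tug1 (-2.86), Dhrs3 (-1.95), Tmem88 (-1.40), Map3k1 (-1.39), Dusp3 (-1.32), Ptafr (-0.89) and Tram1 (-0.87) also differed between barcode classes over all 24 libraries of this population, those of a replicate taken as separate samples. In the pooled fit without barcode class, Dpysl2 stood at -1.95 in Ly6Chi MHCIIlo (adjusted p = 0.319) and -1.67 in Ly6Clo MHCIIlo (1), Gas7 at -1.69 (0.136) and RP24-159O13.1 at -2.51 (0.067), so in that fit the calls ended before barcode class was added. With all 8 groups in 1 fit and the libraries of a replicate added together, Gas7 (0.043) and RP24-159O13.1 kept the call, and Dpysl2 lost it in Ly6Chi MHCIIlo (0.198) and Ly6Clo MHCIIlo (0.772). With barcode class added to the pooled fit, Dpysl2 turned to 0.50 and 0.78, and Gas7 and RP24-159O13.1 moved to -0.39 and -0.77. This takes the barcode effect from Ly6Clo MHCIIhi alone and assumes that it is equal in all populations. The calls in Ly6Chi MHCIIlo also rested on few libraries. For Dpysl2 the adjusted p was 0.0813 to 0.247, and for Gas7 0.0683 to 0.146, without any one replicate other than ctrl replicate 3. For RP24-159O13.1 it was 0.0683 without ctrl replicate 4 and 0.081, 0.063 and 0.11 without ko replicates 2, 3 and 4. The call of Dpysl2 in Ly6Clo MHCIIlo ended without ctrl replicate 3 (0.1) or ko replicate 1 (0.0691) or 4 (0.0602). The count of 3 became 8 without ctrl replicate 3, 1 without ctrl replicate 1 or 2 or ko replicate 1, and 0 without ctrl replicate 4 or ko replicate 2, 3 or 4. The count of 1 in Ly6Clo MHCIIlo became 6 without ctrl replicate 1, 2 without ctrl replicate 4, and 0 without ctrl replicate 3 or ko replicate 1 or 4.

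**Figure D2:**
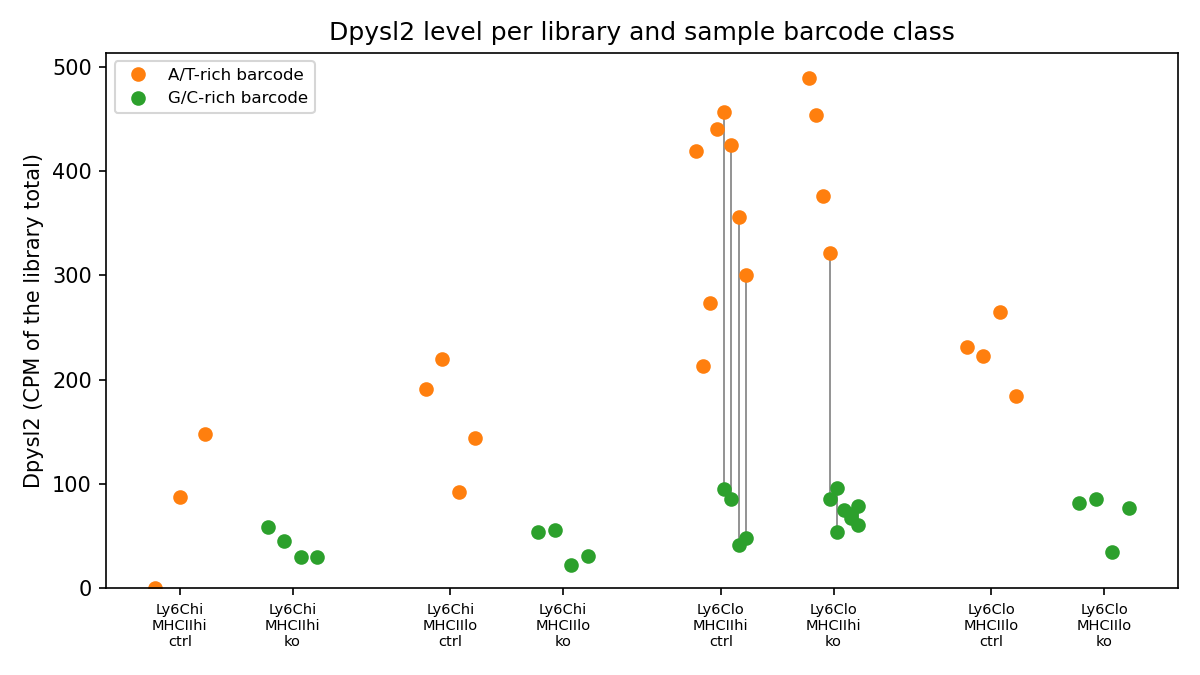
Dpysl2 in CPM of the library total for every library by population and genotype label, coloured by barcode class, with grey lines joining the libraries of one replicate. In Ly6Clo MHCIIhi the G/C-rich library of a replicate lies below its A/T-rich library, a log2 difference of -2.38.

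In Ly6Chi MHCIIhi, the comparison asks about monocytes that carry MHC class II. No gene of 3553 passed in edgeR, 246 had an unadjusted p under 0.05, and DESeq2 called 3. Spink4, a goblet cell peptide, stood at 71.1 ± 42.2 CPM (SD, n = 4) in labelled ko and 2035 ± 2520 CPM (SD, n = 3) in labelled ctrl (log2 fold change -4.76, SE 0.88, adjusted p = 0.546), and the ctrl mean was 609.4 CPM without ctrl replicate 3. Mmp7 (-3.46) and Lyz1 (-3.44), products of Paneth cells, the long noncoding RNA Tug1 (-3.54), which also differed between barcode classes, and Egr1 (-1.15, 130 against 300 CPM) were lower without passing. Basp1, a membrane-bound signalling protein (1.12, 798 against 355 CPM), Znhit1, a chromatin remodelling subunit (1.5), Pdcl3, a chaperone (1.39), Agpat9, a lipid synthesis enzyme (1.89), and Fgr, a myeloid kinase (0.98), were higher without passing (adjusted p = 0.708 each).

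As lists in Ly6Chi MHCIIhi, genes of alternative activation (median 0.59, adjusted camera p = 0.00552), tumour-associated macrophage (0.45, 0.00552), glycolysis (0.44, 0.00552), oxidative phosphorylation (0.20, 0.00552) and MHC class II presentation (0.62, 0.032) lay higher in labelled ko. None of these 5 passed with an estimated correlation (adjusted p = 0.673 each). All 5 passed in the pooled fit and with barcode class in it (0.000793 to 0.0168 in the latter). Arg1, an arginine-degrading enzyme of alternatively activated macrophages, stood at 1560 against 645 CPM (1.19; 364.2 without ctrl replicate 4) and Cd74 at 12140 against 7688 CPM (0.66), neither past the threshold. Neutrophil genes (median -3.18, 0.0492) and ribosomal proteins (-0.26, 0.00116) lay lower, but not with an estimated correlation (0.688 and 0.72). Neither passed in the pooled fit (0.0862 and 0.372) or with barcode class in it (0.0643 each). A fit without libraries under 100000 counts keeps only ctrl replicate 4 (n = 1) against 4 ko replicates, so little can be read from it. In it the neutrophil and ribosomal lists lay higher. Ctrl replicate 1 was rich in neutrophil and red cell transcripts, with 241000 CPM of haemoglobin and other red cell markers against 110 and 1100 in ctrl replicates 3 and 4. Without ctrl replicate 1 the adjusted p was 0.2 for MHC class II, 0.628 for ribosomal proteins and 0.434 for the alternative activation, tumour-associated macrophage, glycolysis and neutrophil lists. The oxidative phosphorylation call ended without ko replicate 1 (0.0753) or 4 (0.0554). The MHC class II call also ended without ko replicate 1 (0.0531), 2 (0.0875) or 3 (0.112). The tumour-associated macrophage call ended without ko replicate 2 (0.112) or 4 (0.0528), and the neutrophil call without ko replicate 1 (0.194), 2 (0.112) or 3 (0.139). The count of 0 genes became 28 without ctrl replicate 4 and 5 without ctrl replicate 1.

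The interaction of genotype and population asks whether the genotype effect differs between the 4 populations. Of 6022 genes, 4 passed, and 400 had an unadjusted p under 0.05. The 4 were Car2, a carbonic anhydrase of red cells and epithelium (adjusted p = 0.0126), Hba-a2 (0.0315), Hbb-bt (0.0315) and Hba-a1 (0.0325). In Ly6Chi MHCIIhi, Hba-a1 stood at 17670 ± 30410 CPM (SD, n = 3) in labelled ctrl and 188 ± 136 CPM (SD, n = 4) in labelled ko, a log2 fold change of -7.17. The log2 fold change was 2.04 in Ly6Chi MHCIIlo, 2.15 in Ly6Clo MHCIIhi and 2.70 in Ly6Clo MHCIIlo. Car2 stood at 595 ± 1024 CPM (SD, n = 3) against 9.63 ± 7.50 CPM (SD, n = 4) in Ly6Chi MHCIIhi. The high means in labelled ctrl come from ctrl replicate 1, without which they were 120.1 CPM for Hba-a1 and 4.35 CPM for Car2 (n = 2). The edgeR count was 0 without that replicate, without any of Ly6Chi MHCIIhi ko replicates 1 to 4, and without Ly6Clo MHCIIlo ctrl replicate 2 or ko replicate 2. It was 15 without Ly6Chi MHCIIhi ctrl replicate 3 and 86 without ctrl replicate 4. DESeq2 called 11 genes and gave no p for any of these 4, so it neither supports nor contradicts their calls.

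Among the Ly6Chi cells, the comparison of MHCIIhi with MHCIIlo asks how monocytes that carry MHC class II differ from those low in it. Genes of blood monocytes were lower in Ly6Chi MHCIIhi. As lists, genes of macrophages and of antigen presentation were higher and those of neutrophils lower, but these did not pass with an estimated correlation (adjusted p = 0.0845 each). Cd74 stood at 10100 ± 3463 CPM (SD, n = 7) against 1853 ± 511 CPM (SD, n = 8), a log2 fold change of 2.38 (SE 0.23, adjusted p = 4.1e-06, higher in 7 of 7). Ly6c2 stood at 557 ± 225 against 1213 ± 256 CPM (-1.16, SE 0.22, adjusted p = 0.00543, lower in 7 of 7). Of 4756 genes, 136 passed, 63 higher and 73 lower, and by edgeR 0 passed with samples labelled ctrl only.

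Of 14 mature macrophage genes in this comparison, 6 rose and 0 fell, with 8 higher adjusted over the list alone. They included the complement genes C1qb (2.02, 1539 against 383 CPM), C1qc (2.02) and C1qa (1.81), whose products tag cells for uptake, and the mannose receptor Mrc1 (1.62). Ccl8, a chemokine of monocytes and macrophages, rose from 28.9 to 323 CPM (3.59), Axl, a receptor for dying cells, by 2.01 and Cd72, an inhibitory receptor, by 2.17. Of 12 tumour-associated macrophage genes, Mmp12, a macrophage elastase (1.57), and Spp1, which encodes osteopontin (1.15, 781 against 361 CPM), rose. Of 12 mature dendritic cell genes 3 rose, Ramp3, a receptor partner protein (1.77), Il4i1, an amino acid oxidase (1.78), and Ccr7, the lymph node homing receptor (1.58). Of 5 T and NK cell genes 3 rose, among them Cd3d (1.74) and Il2rb (2.44), and of 4 B and plasma cell genes Mzb1 alone (3.11). Neither list passed with an estimated correlation (0.0845 and 0.351), and the calls of Cd3d, Il2rb and Mzb1 ended in 8, 10 and 5 leave-outs. B and plasma cell markers summed to 5850 ± 6600 CPM (SD, n = 7) in Ly6Chi MHCIIhi and 1270 ± 2220 CPM (SD, n = 8) in Ly6Chi MHCIIlo, or 511 ± 579 CPM (SD, n = 7) there without ctrl replicate 4. Pxdc1, of little known function, rose by 1.89.

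Of 15 classical monocyte genes 8 fell and 0 rose, or 12 and 1 adjusted over the list alone. F13a1, a clotting factor subunit, fell from 252 to 63.0 CPM (-1.90), and Vcan, a matrix proteoglycan of monocytes, from 226 to 68.3 CPM (-1.62). Cd177 (-1.85), a neutrophil surface protein, and Pi16, a protease inhibitor (-1.99), fell as well. Of 15 neutrophil genes 3 fell, Stfa2l1, a protease inhibitor (-3.54), G0s2, a lipase inhibitor (-2.58), and Csf3r, the G-CSF receptor (-1.34), while Il1r2, a decoy interleukin receptor, rose (1.69, 422 against 130 CPM). Il1f9, which encodes interleukin-36 gamma (-3.34), Nhsl2 (-2.01) and Reg3g, an antibacterial lectin of epithelium (-6.29, 0.621 against 90.6 CPM, or 0 against it without Ly6Chi MHCIIhi ctrl replicate 4), fell.

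In this comparison of the Ly6Chi cells, 14 of 27 lists passed camera, and the classical monocyte list passed both ways (median -1.16, adjusted p = 3.46e-14, and 0.000628 with an estimated correlation). The adjusted p was 4.66e-09 for macrophage (median 0.81) and for neutrophil genes (-1.25), 2.28e-05 for mature dendritic cell (0.43) and T and NK cell genes (1.74), and 0.000327 for MHC class II presentation (1.25). With an estimated correlation it was 0.0845 for these 5 lists. It was 0.000117 for tumour-associated macrophage (0.63), 0.00528 for B and plasma cell (2.58), 0.016 for patrolling monocyte (-0.38) and 0.0123 for cell cycle genes (0.79). It was 0.0291 for epithelial (-0.56) and oxidative phosphorylation genes (0.14), 0.0331 for bacterial sensing (-0.32) and 0.00669 for glycolysis (0.27). With an estimated correlation, the adjusted p of these 8 lists was 0.157 to 0.473. With the replicate number as a block, which pairs these samples, Ccr7 (1.74, adjusted p = 0.0504), the cell cycle list's Tuba1b, a tubulin (0.78 for 0.77, adjusted p = 0.0576), and the oxidative phosphorylation list (0.157) lost the call. Without libraries under 100000 counts, which keeps 1 ctrl replicate of Ly6Chi MHCIIhi, the patrolling monocyte (0.0589), bacterial sensing (0.181) and cell cycle lists (0.181) lost it. In the pooled fit, without and with barcode class, the epithelial (0.152 and 0.161) and oxidative phosphorylation lists (0.301 and 0.295) did not pass.

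Without Ly6Chi MHCIIhi ctrl replicate 4 the 136 genes became 71, without ko replicate 2 they became 82, and without ctrl replicate 1 220. Calls that ended in some leave-outs were those of Ccr7 (13 of 15), Pxdc1 (11), Cd177 (10), Il2rb (10 of 14), Cd3d (8), Mzb1 (5), Spp1 (3), Reg3g (2 of 12) and Il4i1 (1 of 14). Their highest adjusted p was 0.131, 0.117, 0.129, 0.0838, 0.15, 0.136, 0.128, 0.0891 and 0.0799. The list calls that ended were cell cycle without ctrl replicate 1 (0.0866), glycolysis without ctrl replicate 4 (0.0669), and oxidative phosphorylation (up to 0.339, ctrl replicate 4), epithelial (up to 0.104, Ly6Chi MHCIIlo ko replicate 2) and bacterial sensing (up to 0.139, ctrl replicate 1) in 4, 4 and 5 of 15 leave-outs.

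Among the Ly6Clo cells, the comparison of MHCIIhi with MHCIIlo asks what sets antigen-presenting cells of the tumour apart from MHC class II low cells. Ly6Clo MHCIIhi, sorted for MHC class II, was rich in genes of antigen presentation, and Ly6Clo MHCIIlo in genes of neutrophils. Mature dendritic cell genes were higher and tumour-associated macrophage genes lower as lists in Ly6Clo MHCIIhi, but these did not pass with an estimated correlation (adjusted p = 0.137 and 0.0554). Cd74 stood at 15050 ± 1056 CPM (SD, n = 16) against 2917 ± 611 CPM (SD, n = 8), a log2 fold change of 2.37 (SE 0.10, adjusted p = 9.11e-18, higher in 16 of 16). Retnlg stood at 32.7 ± 37.2 against 1873 ± 1344 CPM (-5.80, SE 0.32, adjusted p = 2.87e-14, lower in 16 of 16). Of 4817 genes, 1229 passed, 573 higher and 656 lower, and 325 passed with samples labelled ctrl only.

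All 3 measured MHC class II presentation genes rose, Cd74, its master regulator Ciita (2.33, 169 against 34.3 CPM) and the protease Ctss (0.28). Of 15 mature dendritic cell genes 11 rose and 1 fell. Fscn1, an actin bundler of dendritic processes, rose by 3.99, Ccl22, a CCR4 ligand like Ccl17, from 10.6 to 129 CPM (3.70, SE 0.50, higher in 16 of 16), Ccr7 from 31.2 to 208 CPM (2.67) and Cd83, a maturation marker, from 376 to 1253 CPM (1.74). Ccl17 itself stood at 96.2 ± 230 against 3.96 ± 5.66 CPM (4.18, SE 1.44, adjusted p = 0.0318), with means of 43.99 without Ly6Clo MHCIIhi ctrl replicate 4 and 2.18 without Ly6Clo MHCIIlo ko replicate 2. That call was lost with DESeq2 (1.64, adjusted p = 0.303), with samples labelled ctrl only (6.62, 0.109), in the pooled fit (2.88, 0.158, and 0.164 with barcode class), and without each of Ly6Clo MHCIIlo ctrl replicates 1 to 4 (0.0726, 0.0667, 0.0813 and 0.0788). Il4i1 (2.95), Ramp3 (2.05), Ccl8 (3.23), Serpinb6b, a granzyme inhibitor (2.49), and Plet1, a surface protein of dendritic cell subsets (2.35), rose as well. Of 12 interferon gamma genes 4 rose, among them Fcgr4, an IgG receptor (1.23), and the guanylate-binding protein Gbp7 (0.71). Of 16 immediate early genes 5 rose, Fos from 2061 to 3457 CPM (0.74), Fosb (0.70), Atf3 (0.75) and Dnajb1 (1.44) among them. Of 54 ribosomal protein genes 31 rose and 2 fell, with Rpl39 at 0.60 and Rpsa at -0.82. Of 32 oxidative phosphorylation genes 11 rose, Ndufa4 (0.77) among them, and of 16 mature macrophage genes 6 rose, Pltp, a phospholipid transfer protein (1.07), and Mrc1 (0.84) among them.

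Of 16 neutrophil genes 15 fell. The alarmin S100a8 stood at 166 ± 141 against 5060 ± 2677 CPM (-4.96) and its partner S100a9 at 136 against 5999 CPM (-5.52). Cxcr2, the receptor that draws neutrophils to tissue (-5.12), Camp, an antibacterial peptide precursor (-4.50), Ngp, a granule protein (-4.64), G0s2 (-5.51), Stfa2l1 (-4.62), Wfdc21, a small secreted protein (-4.80), and Il1f9 (-4.66) fell alongside. Of 13 tumour-associated macrophage genes 9 fell, with Spp1 at 665 ± 182 against 1872 ± 406 CPM (-1.51), Arg1 at 827 against 1879 CPM (-1.21), Gpnmb, a lysosomal glycoprotein, at 55.6 against 250 CPM (-2.27) and Cd9, a tetraspanin (-0.90). Of 15 glycolysis and hypoxia genes 5 fell, the lactate exporter Slc16a3 (-1.23) and the enzyme Pkm (-0.49) among them, and of 22 lysosome genes 7 fell and 2 rose, with Cd36, a scavenger receptor (-2.24), Mfge8, a bridge to dying cells (-1.80), and the protease Ctsd (-0.99). Of 12 monocyte genes 5 fell, with Fn1, which encodes fibronectin (-0.77), among them, and S100a4 rose (0.68). Ly6c2 did not pass (29.0 ± 22.4 against 48.8 ± 17.9 CPM, -0.83, adjusted p = 0.0607).

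For Ly6Clo MHCIIhi against MHCIIlo, 14 of 26 lists passed camera. Neutrophil (median -4.56, adjusted p = 9.11e-20) and MHC class II presentation genes (2.33, 4.12e-06) also passed with an estimated correlation (0.000535 and 0.00208). The adjusted p was 3.08e-17 for ribosomal proteins (0.103 with an estimated correlation), 1.32e-07 for oxidative phosphorylation (0.137), 6.15e-06 for mature dendritic cell (0.137) and tumour-associated macrophage genes (0.0554), and 0.00046 for glycolysis (0.427). It was 0.00087 for immediate early (0.427), 0.00454 for interferon gamma (0.454) and 0.0086 for mature macrophage genes (0.454). It was 0.0277 for type I interferon (0.476) and for lysosome genes (0.5), 0.0305 for bacterial sensing (0.454, and 0.0758 in the pooled fit with and without barcode class) and 0.0421 for monocyte genes (0.427), and these 4 calls ended in 5, 6, 6 and 6 of 24 leave-outs. Their highest adjusted p was 0.071 without Ly6Clo MHCIIhi ko replicate 5, 0.112 without Ly6Clo MHCIIlo ctrl replicate 1, 0.0895 without Ly6Clo MHCIIlo ko replicate 3 and 0.059 without Ly6Clo MHCIIhi ctrl replicate 1. Of the type I interferon genes, Zbp1, a nucleic acid sensor (1.30), Ms4a4c (1.23) and Isg15, a ubiquitin-like modifier (0.99), rose. The call of Isg15 ended in 10 of 24 leave-outs (up to 0.0998, Ly6Clo MHCIIlo ko replicate 4) and that of Ms4a4c without Ly6Clo MHCIIlo ctrl replicate 3 (0.0619) or ko replicate 4 (0.0609). Of the bacterial sensing genes Clec4d, a lectin receptor (-1.28), and the formyl peptide receptor Fpr1 (-1.09) fell.

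Among MHCIIhi cells, the comparison of Ly6Clo with Ly6Chi asks how antigen-presenting cells low in Ly6C differ from those high in it. Ly6Clo MHCIIhi held more transcript of mature macrophage, lysosome and lipid handling genes, and less of monocyte genes. Mature dendritic cell genes were higher and NF-kB targets lower as lists, but these did not pass with an estimated correlation (adjusted p = 0.494 and 0.419). Apoe, a lipid carrier of macrophages, stood at 26380 ± 5812 CPM (SD, n = 16) against 6865 ± 1415 CPM (SD, n = 7), a log2 fold change of 1.95 (SE 0.16, adjusted p = 1.82e-09, higher in 16 of 16). Ly6c2 stood at 27.6 ± 21.2 against 566 ± 221 CPM (-4.36, SE 0.26, adjusted p = 1.62e-12, lower in 16 of 16). Of 5541 genes, 873 passed, 460 higher and 413 lower, and 61 passed with samples labelled ctrl only.

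Of 16 mature macrophage genes 12 rose and 0 fell, with C1qa at 3119 against 688 CPM (2.16), C1qb at 6064 against 1580 CPM (1.94) and Mrc1 (1.17). Of 22 lysosome genes 16 rose, Axl (1.65, 296 against 84.9 CPM), the growth factor precursor Grn (1.01) and the proteases Ctsd (1.10) and Ctsb (0.95) among them. Of 17 cholesterol and lipid genes 7 rose, with Lipa, a lysosomal lipase (1.24), Hmgcs1, of sterol synthesis (1.60), and Lpl, lipoprotein lipase (1.46). Of 16 mature dendritic cell genes 6 rose, with Fscn1 (4.07), Ccl22 (3.89, 123 against 8.34 CPM), Tbc1d4 (2.90) and Ccr7 (1.79). Cadm1, an adhesion protein of the dendritic cells that cross-present (3.95, 51.1 against 2.41 CPM, or 0.749 without Ly6Chi MHCIIhi ko replicate 4), Dnase1l3, a secreted DNase (3.73), Adamdec1, a protease of gut macrophages (2.94), Vcam1, an adhesion receptor (2.92), and Tnfsf13b, the B cell factor BAFF (3.36), rose too, as did Lilra5 (3.4) and the collagen Col14a1 (2.91). Dnase1l3 differed between barcode classes as well (-1.44 over those 24 libraries). Of the MHC class II genes, Cd74 (0.51, 14330 against 10380 CPM), Ctss (0.54) and Ciita (0.75) rose. Of the immediate early genes 6 of 16 rose, Egr1 (1.09) and Fos (0.71) among them.

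Of 14 classical monocyte genes 13 fell, with Chil3, a chitinase-like protein, at 24.3 against 259 CPM (-3.59; 172.4 without Ly6Chi MHCIIhi ko replicate 4), Hp, haptoglobin, at 210 against 761 CPM (-2.02), and Vcan (-3.11). Of 19 NF-kB genes 6 fell and 1 rose, with Clec4e, a receptor for fungal and mycobacterial lipids (-1.67, 304 against 951 CPM), Osm, a cytokine of gut inflammation (-1.21, 506 against 1233 CPM), Il23a, a subunit of interleukin-23 (-1.68), and the chemokine Ccl7, which rose (1.40). Of 12 bacterial sensing genes 7 fell, among them Cd14, a lipopolysaccharide receptor (-0.82, 3666 against 6604 CPM), Tlr2 (-0.71) and the brake Irak3 (-1.28). Of 12 alternative activation genes Tgm2 (-1.75, 791 against 2872 CPM), the growth factor Tgfb1 (-0.96) and 1 other fell, and of 15 glycolysis genes Slc16a3 (-0.99), Pfkp (-0.95) and the other two fell. Of 58 ribosomal protein genes 9 fell, Rps14 (-0.44) among them. Of 14 type I interferon genes 5 fell, Ms4a4c (-1.32) among them, and Bst2, which tethers viruses to cells, rose (1.06). Of 13 neutrophil genes 10 fell, Camp at 7.17 against 1597 ± 4055 CPM (-6.98), Ngp (-6.78), S100a8 (-4.36), S100a9 (-4.44), Wfdc21 (-4.22) and Hdc, which makes histamine (-1.97).

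Ly6Chi MHCIIhi ctrl replicate 1 carried much of the neutrophil and red cell transcript in this comparison. Without it Camp stood at -3.03 (adjusted p = 0.000417; mean there 64.93 CPM) and Ngp at -2.27 (0.0166), both still past the threshold, S100a8 at -0.88 (adjusted p = 0.124), S100a9 at -0.96 (0.148) and Wfdc21 at -1.55 (0.0531), and the haemoglobin genes turned direction. These were Hbb-bt (from -5.54 to 0.83), Hbb-bs (from -5.36 to 0.44), Hba-a1 (from -5.34 to 0.88) and Hba-a2 (from -5.24 to 0.83). Calls also ended for Cd74 without ctrl replicate 3 (0.0603), for Ctss without that replicate (0.0567) or ko replicate 4 (0.0532), for Zbp1 (from -1.12 to -0.66, 0.177) and Irf7 (from -0.80 to -0.65, 0.0531) without ko replicate 3, for Il23a without ko replicate 2 (0.113), for Cd14 without ctrl replicate 4 (0.0508), and for Ciita in 9 of 23 leave-outs (up to 0.166). Irf7, a master regulator of interferon, also lost its call without ctrl replicate 4 (0.0508).

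In the MHCIIhi cells 14 of 28 lists passed camera, 4 of them also with an estimated correlation. These 4 were classical monocyte (median -1.85, adjusted p = 4.07e-17, and 0.000176 with an estimated correlation), mature macrophage (1.25, 1.13e-17, and 0.0117), lysosome (0.67, 1.64e-14, and 0.0457) and cholesterol genes (0.51, 0.00103, and 0.0457). The adjusted p was 6.17e-05 for NF-kB targets (median -0.65), 0.000139 for bacterial sensing (-0.73), 0.00018 for neutrophil (-2.35) and glycolysis genes (-0.39), 0.000248 for ribosomal proteins (-0.15), 0.00444 for immediate early (0.35), 0.00517 for MHC class II presentation (0.54) and 0.00701 for alternative activation (-0.35). For these 8 lists it was 0.14 to 0.497 with an estimated correlation. Mature dendritic cell (0.34, 0.0339) and type I interferon genes (-0.64, 0.0391) had adjusted p = 0.494 and 0.572 with an estimated correlation. Their calls ended in 6 and 9 of 23 leave-outs, up to 0.117 without Ly6Chi MHCIIhi ko replicate 1 and 0.168 without ko replicate 3. The mature dendritic cell call also ended without libraries under 100000 counts (0.0763), which keeps 1 ctrl replicate of Ly6Chi MHCIIhi.

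Among MHCIIlo cells, the comparison of Ly6Clo with Ly6Chi asks how MHC class II low cells differ between low and high Ly6C. Of 4336 genes, 1623 passed, 835 higher and 788 lower, and 766 passed with samples labelled ctrl only. Ly6Clo MHCIIlo carried the genes of mature macrophages and lysosomes, and Ly6Chi MHCIIlo those of monocytes. Tumour-associated macrophage genes were higher and NF-kB targets lower as lists in Ly6Clo MHCIIlo, but these did not pass with an estimated correlation (adjusted p = 0.0513 and 0.124). C1qc stood at 2569 ± 529 against 160 ± 55.3 CPM (SD, n = 8 each), a log2 fold change of 4.01 (SE 0.18, adjusted p = 4.19e-14, higher in 8 of 8). Ly6c2 stood at 48.8 ± 17.9 against 1286 ± 272 CPM (-4.73, SE 0.20, adjusted p = 6.44e-15, lower in 8 of 8).

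Of 16 mature macrophage genes 14 rose, with C1qa (3.82), Apoe at 23150 ± 5047 against 3483 ± 899 CPM (2.73), Mrc1 (2.03) and Cd63 (2.94). Of 13 tumour-associated macrophage genes 11 rose, with Spp1 at 1873 ± 411 against 383 ± 102 CPM (2.29), Gpnmb (4.07) and Mmp12 at 1420 against 103 CPM (3.83). Of 22 lysosome genes 18 rose and 1 fell, with Mfge8 at 1232 ± 512 against 71.1 ± 61.6 CPM (4.13), Ctsd (2.12), Cd36 (3.52), Axl (3.39) and the protease Lgmn (1.76). Of 15 cholesterol and lipid genes 9 rose and 2 fell, with Lpl (3.03), Lipa (2.03) and Apoc1, an apolipoprotein (-2.02). Igf1, a growth factor of tissue macrophages (4.31, 129 against 6.21 CPM), Adamdec1 (4.37, 146 against 6.49 CPM), Col14a1 (4.51), the collagenase Mmp2 (3.99) and the transcription factor Bhlhe41 (4.0) rose as well.

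Of 15 classical monocyte genes 13 fell, with F13a1 (-4.34, 13.2 against 267 CPM), Vcan (-4.21), Chil3 (-4.16), Plac8, a monocyte protein, at 277 against 3517 CPM (-3.69), and S100a4 (-2.74). Of 19 NF-kB genes 13 fell and 1 rose, with Osm at 680 against 1802 CPM (-1.40), the neutrophil chemokine Cxcl2 at 6814 against 11660 CPM (-0.77), Nfkbia, the NF-kB inhibitor (-1.20), and Clec4e (-1.44). Of 11 type I interferon genes 8 fell, Ms4a4c (-3.34), Zbp1 (-2.39) and Irf7 (-1.78) among them, and Bst2 rose (1.01). Of 12 bacterial sensing genes 8 fell, with Cd14 at 3288 against 8321 CPM (-1.33), Nod2, a sensor of bacterial wall peptides (-2.21), and Tlr2 (-0.70). Of 10 alternative activation genes 7 fell, Tgm2 (-1.68) and Socs3, a cytokine signalling brake (-1.40), among them, and 3 rose. Of 53 ribosomal protein genes 29 fell and 1 rose, with Rps9 at -0.89. Dmkn, a secreted protein first known from skin (-5.33, 4.27 against 192 CPM), Prtn3, a protease of granulocyte precursors (-4.97), and Timp1, a protease inhibitor (-3.19, 126 against 1108 CPM), fell. The Paneth cell defensin Defa24, one of several near-identical copies, fell as well (-3.65, adjusted p = 0.015), a call that ended without Ly6Chi MHCIIlo ctrl replicate 3 (-1.61, 0.256) or ko replicate 2 (-2.50, 0.117).

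In the MHCIIlo cells 10 of 26 lists passed camera, and each passed in every leave-out. Classical monocyte (median -2.45, adjusted p = 1.25e-13), lysosome (1.02, 1.64e-12) and mature macrophage genes (1.84, 2.02e-11) passed with an estimated correlation too (0.0116, 0.0486 and 0.0486). The adjusted p was 2.09e-07 for tumour-associated macrophage (median 1.16), 3.69e-08 for ribosomal proteins (-0.41), 9.48e-06 for NF-kB targets (-0.67), 0.00231 for type I interferon (-1.53) and bacterial sensing (-0.70), 0.0181 for cholesterol (0.67) and 0.0275 for alternative activation genes (-0.92). With an estimated correlation these were 0.0513, 0.403, 0.124, 0.435, 0.218, 0.143 and 0.124. The neutrophil list did not pass (5 of 16 rose, 3 fell, adjusted p = 0.497).

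**Figure D3:**
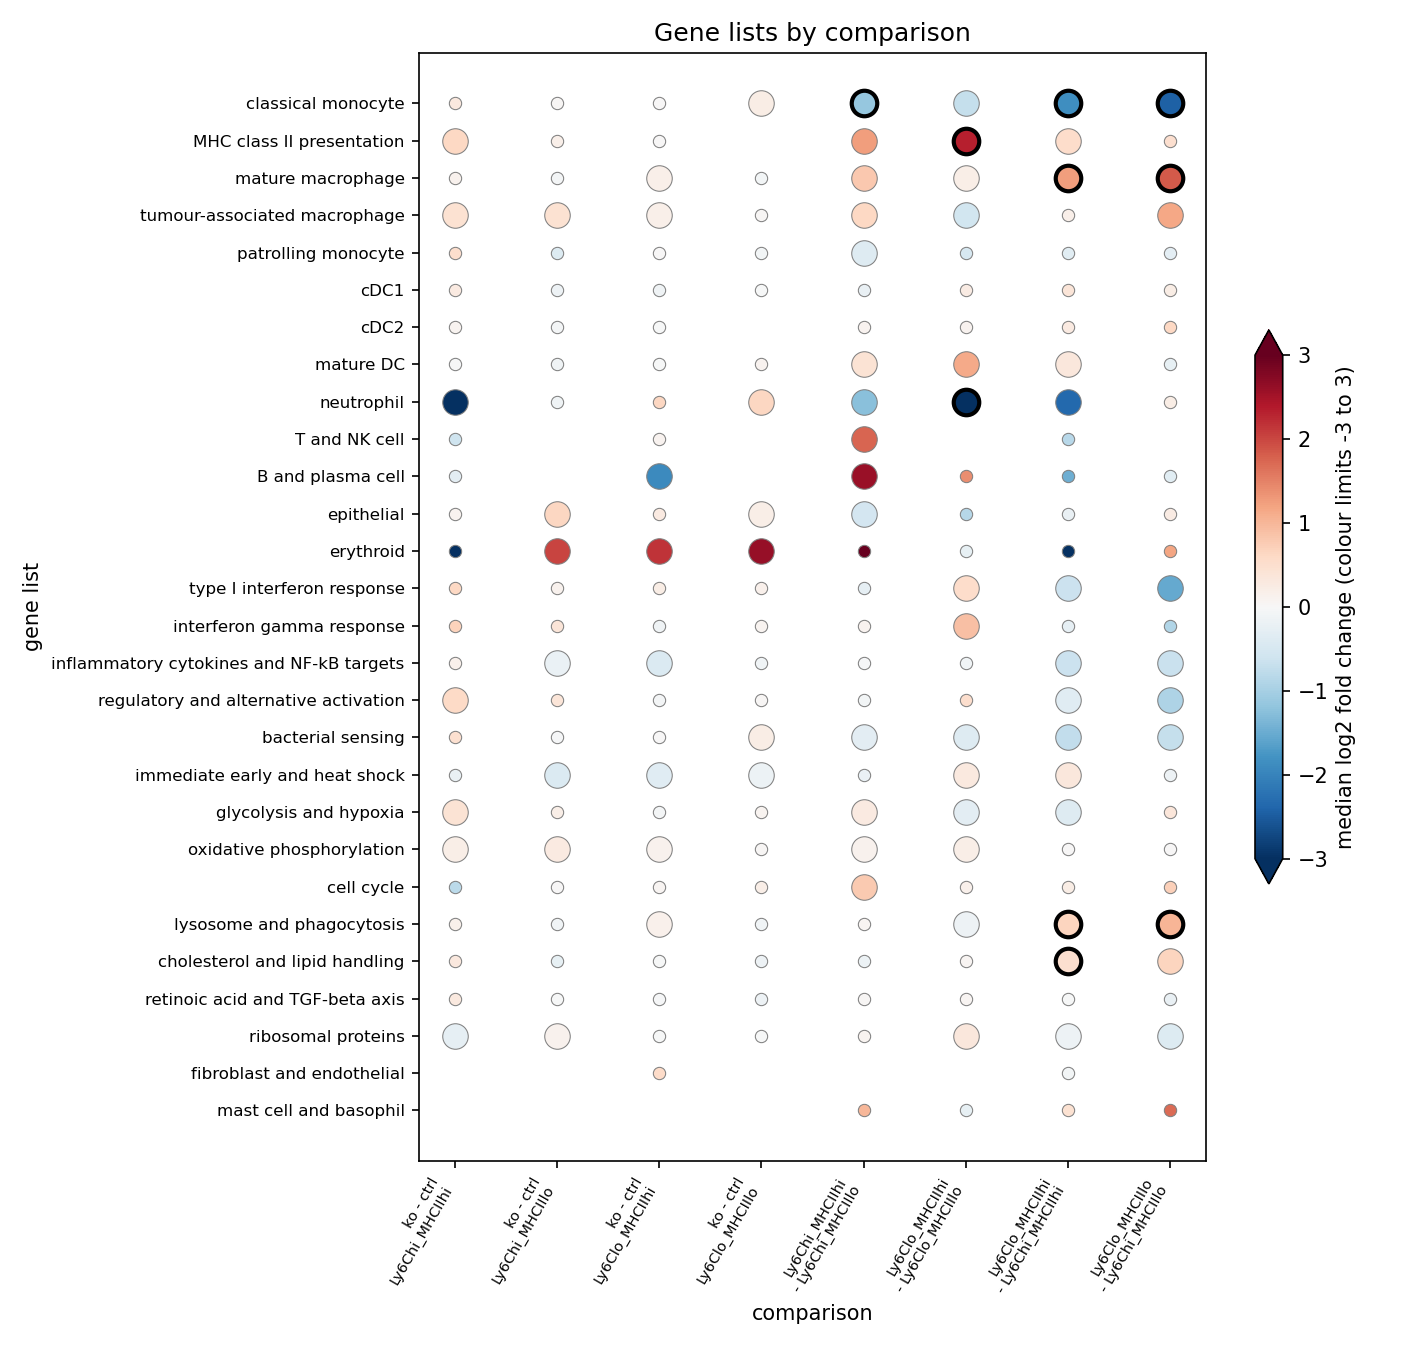
Gene lists against the 8 pairwise comparisons, with colour for the median log2 fold change from -3 to 3, large dots for lists past an adjusted camera p of 0.05, and a thick black edge where the list also passed with an estimated correlation. The black edges number 10, all in comparisons of populations.

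**Figure D4:**
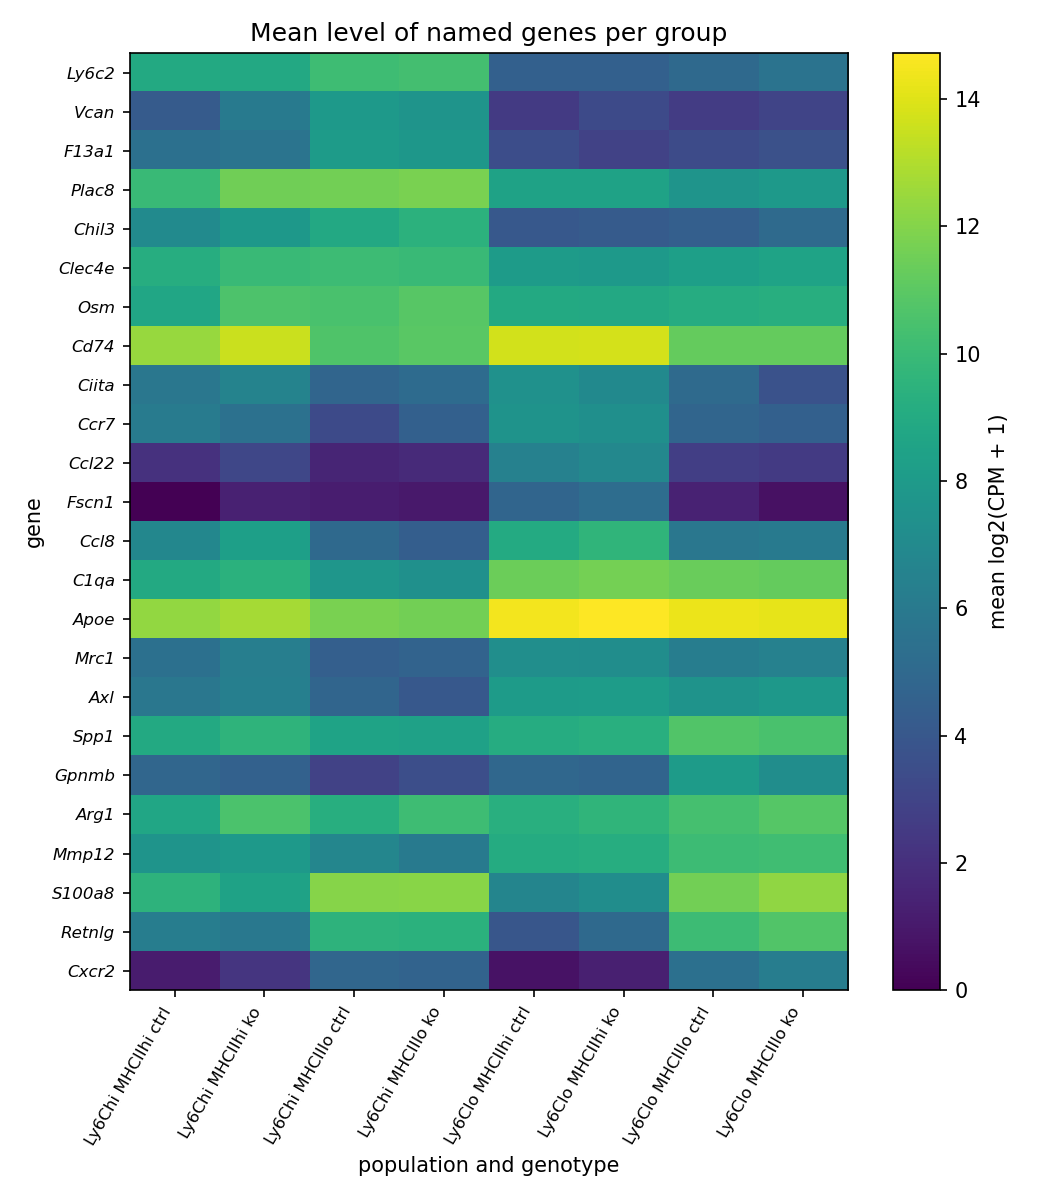
Mean log2(CPM + 1) of 24 named genes in the 8 groups of population and genotype label. Ly6c2 and Vcan are highest in the Ly6Chi groups, Cd74 and Ccl22 in Ly6Clo MHCIIhi, and Spp1 and Gpnmb in Ly6Clo MHCIIlo.

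Markers of other cell types were summed per replicate to show what else the gates held. Neutrophil markers summed to 10900 ± 24200 CPM (SD, n = 7) in Ly6Chi MHCIIhi, 14200 ± 5810 CPM (SD, n = 8) in Ly6Chi MHCIIlo, 1360 ± 435 CPM (SD, n = 16) in Ly6Clo MHCIIhi and 14400 ± 7610 CPM (SD, n = 8) in Ly6Clo MHCIIlo. The mean of Ly6Chi MHCIIhi rests on ctrl replicate 1 (65900), without which it was 1770 ± 726 CPM (SD, n = 6). In the same order, epithelial markers summed to 610 ± 532, 900 ± 399, 444 ± 201 and 876 ± 713 CPM. Haemoglobin and other red cell markers summed to 35200 ± 90800, 803 ± 914, 1620 ± 2780 and 1830 ± 2100 CPM. These were 849 ± 640 CPM (SD, n = 6) in Ly6Chi MHCIIhi without ctrl replicate 1 (241000), 971 ± 969 CPM (SD, n = 15) in Ly6Clo MHCIIhi without ko replicate 6, and 1160 ± 974 CPM (SD, n = 7) in Ly6Clo MHCIIlo without ko replicate 2. Mast cell and basophil markers summed to 262 ± 273, 171 ± 263, 391 ± 505 and 530 ± 489 CPM (in Ly6Chi MHCIIlo 98.7 ± 179 without ko replicate 4), and stromal markers to 181 ± 102, 160 ± 111, 168 ± 99.7 and 124 ± 62.5 CPM. Eosinophil markers summed to at most 35.2 ± 33.5 CPM and plasmacytoid dendritic cell markers to at most 59.4 ± 91.0 CPM (27.3 ± 35.8 without Ly6Chi MHCIIhi ctrl replicate 1). Of 36 comparisons of labelled ko with labelled ctrl, 9 marker lists in 4 populations, 2 had an unadjusted exact permutation p under 0.05 and 0 passed after adjustment (smallest adjusted p = 0.459). Both were red cell markers, higher in labelled ko of Ly6Clo MHCIIhi (2770 against 476 CPM, p = 0.0127) and Ly6Clo MHCIIlo (3160 against 508 CPM, p = 0.0286). The mean of 2770 was 1540 without ko replicate 6, that of 3160 was 2030 without ko replicate 2 and that of 508 was 230 without ctrl replicate 1. The unadjusted p was at most 0.0443 in any leave-out of Ly6Clo MHCIIhi and above 0.05 in 5 of 8 of Ly6Clo MHCIIlo (up to 0.114). With 3 or 4 replicates per genotype 0.0286 is the smallest p this test can give, so in those 3 populations hardly any difference could pass over 36 tests.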

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

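Of the tests in this part, those of barcode class and genotype on Dpysl2 and Gas7, of the spread of Ccl17, and of the library and genotype behind the interaction genes, with its carry-over, were chosen only after the result was seen. A replicate was singled out where its distance to the nearest other replicate took up most of its group's range (Dixon's test). Chance does this in about 1 of 20 groups of normally distributed values, a rate that measures of few counts need not keep. It was found for 23 of 106 groups over 15 measures, many of which share samples and counts.

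Several of these replicates stood apart in markers of other cell types. B and plasma cell markers reached 28100 CPM in Ly6Clo MHCIIhi ctrl replicate 2 (next 8450), 6600 in Ly6Chi MHCIIlo ctrl replicate 4 (next 870), 1620 in Ly6Chi MHCIIlo ko replicate 1 (next 99.6) and 297 in Ly6Clo MHCIIlo ko replicate 2 (next 68.9). Neutrophil markers reached 2370 CPM in Ly6Clo MHCIIhi ctrl replicate 3 (next 1560) and 2390 in ko replicate 7 (next 1520). Red cell markers reached 11400 CPM in Ly6Clo MHCIIhi ko replicate 6 (next 3340) and 957 in Ly6Chi MHCIIlo ctrl replicate 1 (next 61.4). Mast cell and basophil markers reached 1510 CPM in Ly6Clo MHCIIlo ko replicate 3 (next 389) and 1050 in ctrl replicate 3 (next 248). Eosinophil markers reached 110 CPM in Ly6Clo MHCIIlo ko replicate 3 (next 18.9), 3.78 in Ly6Chi MHCIIhi ko replicate 1 (next 0) and 3.51 in Ly6Chi MHCIIlo ko replicate 3 (next 0). T and NK cell markers reached 477 CPM in Ly6Chi MHCIIhi ko replicate 4 (next 247), and stromal markers were lowest in ko replicate 2 of that population (66.4 CPM, next 170). Plasmacytoid dendritic cell markers reached 34.1 CPM in Ly6Chi MHCIIlo ctrl replicate 3 (next 7.87).

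The other values that stood apart belong to single genes and a total. Gas7 reached 321 CPM in Ly6Clo MHCIIhi ctrl replicate 1 (next 203) and 117 in Ly6Clo MHCIIlo ko replicate 1 (next 85.1). RP24-159O13.1 reached 50.7 CPM, from 3 counts, in Ly6Clo MHCIIhi ctrl replicate 2 (next 21.8), and Dpysl2 was lowest in Ly6Clo MHCIIlo ko replicate 3 (31.5 CPM, next 73.0). Car2 reached 26.5 CPM in Ly6Chi MHCIIlo ko replicate 4 (next 10.5), and Ccl17 3.73 CPM, from 1 count, in Ly6Clo MHCIIlo ctrl replicate 3 (next 0). The total count was lowest in Ly6Chi MHCIIhi ko replicate 3 (133000, next 271000). The genotype effect differed between populations by the interaction test for Car2 (adjusted p = 0.0126), Hba-a1 (0.0325), Hba-a2 (0.0315) and Hbb-bt (0.0315).

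The first pattern is the drop of Dpysl2 and Gas7 in labelled ko of Ly6Chi MHCIIlo and of Dpysl2 in Ly6Clo MHCIIlo, where all labelled ko libraries have G/C-rich barcodes. Within replicates of Ly6Clo MHCIIhi that have libraries of both classes, the median log2 difference of these 2 genes, G/C-rich minus A/T-rich, was -1.84, which is consistent with an effect of the barcode. A genotype effect on them shared with Ly6Clo MHCIIhi is argued against by a median log2 fold change of -0.0125 there with barcode class in a fit of library 1 of each replicate (SE 0.175 for Dpysl2 and 0.200 for Gas7), a fit in which barcode class equals replicates 1 to 4 against 5 to 8, whereas one confined to the other populations cannot be told apart from barcode class, and RP24-159O13.1 was under the filter in these tests. The genes lower with G/C-rich barcodes (76 with a sequence) had longer runs of A inside their transcripts, with a mean longest run of 10.1 against 8.64 in genes of like length (permutation p = 0.0036 over 10000 draws), so priming at such runs may play a part. Across genes, which are not independent replicates, genotype folds correlated with barcode folds over all Ly6Clo MHCIIhi libraries by 0.104 in Ly6Chi MHCIIhi, 0.319 in Ly6Chi MHCIIlo and 0.301 in Ly6Clo MHCIIlo.

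The second pattern is the spread of Ccl17 over the replicates labelled ctrl in Ly6Clo MHCIIhi, from 0 to 763 CPM. Depth is argued against, since ctrl replicates 1, 3 and 7, within the ko range, had totals for 63.3, 20.9 and 99.9 Ccl17 counts at the rate of all 8 replicates and held 3, 0 and 1. Ctrl replicate 8 was low as well, with 5 counts against 72.9, though above the ko range at 9.66 CPM. A lower share of mature dendritic cells is argued against for replicates 3 and 7, where Ccl22, a product of the same cells, stood at 73.3 and 115 CPM, within the 33.8 to 246 CPM of the ctrl replicates above the ko range. In replicate 1 Ccl22 stood at 28.4 CPM from 13 counts, so a lower share cannot be told apart there. An exchange with a labelled ko replicate cannot be told apart. These hold or allow up to 12.4 CPM (75.2 in ko replicate 6), above ctrl replicate 8. A wrong label without a partner, or a change in the subset of dendritic cells that makes Ccl17, stays open as an untested hypothesis.

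The third pattern is the interaction of Car2 and the haemoglobin genes, which may come from a single library, Ly6Chi MHCIIhi ctrl replicate 1, rich in red cell and neutrophil transcripts. Without it the interaction test called 0 genes, but 6 other leave-outs of 39 also gave 0, so the median unadjusted p of the 4 genes was examined as well. It was 0.525 without that replicate and at most 0.000155 without any other. An opposite genotype effect on haemoglobin in this population cannot be told apart, because the remaining ctrl libraries gave a median log2 fold change of 0.31 from n = 2. Carry-over of that library into Ly6Clo MHCIIhi is argued against by Camp and Ngp, at 0.194 of the counts it would bring (101 against 520), while haemoglobin differed up to 39.7-fold between libraries of a single replicate.

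Other splits of the same samples show which counts of genes chance can give. For labelled ko against ctrl, chance cannot be excluded in Ly6Chi MHCIIlo (3 genes, up to 9 in other splits, 3 of 35 with at least as many) and Ly6Clo MHCIIlo (1 gene, up to 7, 7 of 35). In Ly6Chi MHCIIhi and Ly6Clo MHCIIhi the real groups gave 0 genes, which any split reaches (35 of 35 and 100 of 100, up to 2 and 3 genes), so the splits decide nothing there. Nor can it be excluded for the interaction (4 genes, up to 7 in other splits, 11 of 100). Chance is unlikely, down to 1 in 100 splits, for the populations, where only the real one gave as many. Ly6Chi MHCIIhi against MHCIIlo gave 136 genes, others up to 2, and 5 splits that part all 7 pairs gave 0. Ly6Clo MHCIIhi against MHCIIlo gave 1229 (up to 58). Ly6Clo against Ly6Chi gave 873 in MHCIIhi (up to 37) and 1623 in MHCIIlo (up to 834). Why a split gave 834 genes was not examined, and a split near the real one would keep part of its difference.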

How the results depend on the processing

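The pooled fit (all 8 groups, each library as its own sample), barcode class in it and the fit without libraries under 100000 counts were chosen after seeing the data, and the last keeps a single ctrl replicate of Ly6Chi MHCIIhi, so little can be read from it there. Where no cause is named, the cause was not tested. Of 212 named gene results past the threshold, 115 kept direction and threshold in every setting run and 171 in all but the leave-outs and the fits of samples labelled ctrl only.

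Counts of genes for labelled ko against ctrl, in the order Ly6Chi MHCIIhi, Ly6Chi MHCIIlo, Ly6Clo MHCIIhi and Ly6Clo MHCIIlo, were 0, 3, 0 and 1. They were 3, 14, 0 and 2 with the DESeq2 test and, with no low-count filter, 1.1e+02 (rounded), 61, 57 and 24. They were 65, 0, 2 and 0 in the pooled fit and 21, 0, 2 and 1 with barcode class in it, the last a different gene, since 0 were shared. All 8 groups in 1 fit gave 36, 3 (2 of them among the first 3), 2 and 0. In Ly6Clo MHCIIhi each library as its own sample gave 1, and the number set gave 0, which with library 1 only is the same model as barcode class. Libraries under 100000 counts left out gave 4 in Ly6Chi MHCIIhi, where a single ctrl sample is then assumed to vary like the others. Leave-outs gave 0 to 28, 0 to 8, 0 to 0 and 0 to 6.

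Ly6Chi MHCIIhi against MHCIIlo (136) gave 304 without the filter, 326 in the pooled fit, 340 with barcode class in it and 0 with samples labelled ctrl only, and 71 to 220 over leave-outs. Ly6Clo MHCIIhi against MHCIIlo (1229, 573 higher) gave 1370 without the filter, 797 higher. With ctrl only, that is fewer samples, it gave 325, and Ly6Clo against Ly6Chi 61 (873) in MHCIIhi and 766 (1623) in MHCIIlo. Leave-outs gave 1077 to 1336, 698 to 1002 and 1552 to 1695. The interaction (4) gave 11 with DESeq2, which gave no p for any of the 4, 1.1e+02 (rounded) without the filter, 1 with all libraries kept, 12 with each library as its own sample, 12 with barcode class added to that, 0 without libraries under 100000 counts and 0 to 86 over leave-outs.

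The replicate number as a block, which pairs samples only in Ly6Chi MHCIIhi against MHCIIlo (142 genes), changed no call there beyond those named. There every pair exceeded a correlation of 0.1, though only 4 of 7 correlated best with their own number. Elsewhere not every pair did, and samples are taken to share only a number. The block gave 712, 445 and 1620 genes in the other population comparisons, in the order above, and 0, 4, 0 and 4 for labelled ko against ctrl. For the interaction the block, added after seeing the data, gave 5 genes, 3 of them among the 4.

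The Ccl17 level difference was -2.51 to -3.88 over leave-outs, -3.37 and -2.55 with pseudocounts of 0.5 and 5, and -3.22 on library totals. Past camera were 80 list results, and 10 with an estimated correlation. Without libraries under 100000 counts the neutrophil (0.376) and ribosomal lists (0.459) in Ly6Chi MHCIIhi ko against ctrl turned up. Dpysl2 stood at -1.95 and -1.67 in the pooled fit and turned to 0.50 and 0.78 with barcode class in Ly6Chi MHCIIlo and Ly6Clo MHCIIlo. In Ly6Clo against Ly6Chi MHCIIhi, the same depth minimum turned Hbb-bt (0.38), Hba-a1 (0.34) and Hba-a2 (0.31). Leave-outs moved Hbb-bt from -6.14 to 0.83, Hbb-bs from -5.91 to 0.44, Hba-a1 from -5.92 to 0.88 and Hba-a2 from -5.84 to 0.83. Depth limits low genes: 5 libraries held under 100000 counts.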

Other observations

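The comparisons of populations also hold genes of dendritic cell subsets, TGF-beta signalling and the cell cycle, whose lists did not pass camera in the comparisons given here and whose members were chosen after their values were seen. Against Ly6Clo MHCIIlo, Ly6Clo MHCIIhi held more Batf3, a factor of cross-presenting dendritic cells (77.7 against 18.1 CPM, log2 fold change 2.08, SE 0.31, adjusted p = 8.86e-06), and more Cd209a, a lectin of another dendritic cell subset (73.9 against 17.2 CPM, 2.02, adjusted p = 0.000333). Cd24a, a glycoprotein of dendritic cells and neutrophils, was lower (-1.89, adjusted p = 5.95e-07). Against Ly6Chi MHCIIhi the folds were 1.38 for Batf3 (adjusted p = 0.00119) and 1.25 for Cd209a (0.0225). The adjusted camera p of the cross-presenting and the other dendritic cell lists was 0.353 and 0.739 against Ly6Clo MHCIIlo, and 0.093 and 0.184 against Ly6Chi MHCIIhi.

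Both receptor chains for TGF-beta were higher in the Ly6Clo cells. Tgfbr1 stood at 157 CPM in Ly6Clo MHCIIlo and 44.3 CPM in Ly6Chi MHCIIlo (1.85, adjusted p = 4.63e-07), and Tgfbr2 differed by 1.34 (0.00011). In the MHCIIhi cells the folds were 1.22 (0.00146) and 1.06 (0.00486). The ligand gene Tgfb1 went the other way in MHCIIlo cells (-1.13), as did Rara, a retinoic acid receptor (-1.40, adjusted p = 5.3e-06). Of the cell cycle genes, Top2a, a topoisomerase of dividing cells (1.44, adjusted p = 0.00296), and Mki67, a marker of division (1.44, 0.00421), were higher in Ly6Clo MHCIIlo than in Ly6Chi MHCIIlo. The adjusted camera p was 0.649 for the TGF-beta and retinoic acid list and 0.0949 for the cell cycle list there.

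The second libraries of 8 replicates in Ly6Clo MHCIIhi varied more than counting alone, with a chi-square per degree of freedom of 1.74 to 2.53, and 5 of 8 correlated best with the first library of the same replicate. Ccl22, the neighbour of Ccl17 (chromosome 8, 94745590 to 94751699, plus strand), stood at 135 CPM in labelled ko and 116 CPM in labelled ctrl of Ly6Clo MHCIIhi (log2 fold change 0.12, SE 0.32), and was chosen after its values were seen.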
